A study of Steinernema carpocapsae and Caenorhabditis elegans with 54 samples.

How the data were processed

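PolyA RNA of heads, tails and whole bodies was sequenced as unstranded paired-end reads of 43 bp, with libraries made as in a Smart-seq2 protocol for single worms, per the labels' protocols. The submitters' processing notes name Bowtie 1.0.0, RSEM and limma, without saying which step each tool did. The genome build and the annotation are not given in the sources used here. The authors deposited 1 table of TPM per species, with 1 column per library, replicates not pooled, and each column summing to 1000000 over all genes of the table. Read counts were not used here, so the depth of each library and the counting error of each value are unknown.

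For S. carpocapsae 30957 genes were listed, of which 218 read 0 in every library, and for C. elegans 47249 genes, of which 18502 did. Of the C. elegans IDs, 43985 had a symbol in the gene name table and 46781 stood in the Ensembl 115 annotation of WBcel235, which gave biotype and chromosome. Of the S. carpocapsae IDs, 0 matched the RefSeq gene table, so names, gene lists and tests across species were not analysed here. All 54 libraries were mapped to a species, a body part and a stage or sex by their column names.

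Genes with at least 1 TPM in at least 3 of the 27 libraries of a species were tested, 25082 in S. carpocapsae and 24134 in C. elegans. For each species, limma 3.58.1 in R 4.3.3 fitted log2 of TPM plus 1 with 9 group means over all 27 libraries, leaving 18 residual degrees of freedom, followed by eBayes with a trend. Each comparison was adjusted by Benjamini-Hochberg at 0.05, with tests on both sides. The 9 comparisons per species were male against female or hermaphrodite in each body part, IJ or dauer against the mean of both adult groups in each body part, and head against tail in each stage or sex. The interaction asked whether head minus tail differed between males and females or hermaphrodites.

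Gene lists of C. elegans were tested with camera at a preset correlation of 0.01, adjusted over all 250 pairs of list and comparison. The 25 lists were major sperm proteins, spermatogenesis, oocyte and eggshell, vitellogenins, germ line and meiosis, sex determination and dosage compensation, male-specific sensory neurons, pharynx, body wall muscle, intestine, cuticle collagens of the dumpy, roller, blister and squat classes, pan-neuronal genes, ciliated sensory neurons, FMRFamide-like peptides, insulin-like peptides, neurotransmitter pathways, dauer signalling, stress protection, small heat shock proteins, ribosomal proteins, histones, cytosolic oxidative phosphorylation, mitochondrially encoded transcripts, DNA replication and mitosis, and antimicrobial genes. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined.

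The rule took, in each comparison, the 5 largest and 5 smallest log2 fold changes (2 of each where genes have no symbol) among genes past 0.05 whose groups did not overlap and whose higher group mean was at least 10 TPM. It added up to 4 members of each described list with the smallest adjusted p, and in the sex comparisons of C. elegans always vit-2, mab-3, lov-1, pkd-2, xol-1, her-1, tra-1, myo-2 and rab-3. At most 2 copies of near-identical families were named in a comparison. The interaction took 4 genes of each sign with a mean of at least 10 TPM in 1 of the 4 groups.

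Each result was recomputed with a fit of only the libraries compared, a pseudocount of 0.1, no filter, a term for the replicate number, array weights, median-of-ratios scaling of TPM, each library left out in turn, and, for the lists, camera with an estimated correlation or the replicate term. Alternatives added after the data were examined were rescaling without ribosomal RNA in C. elegans and without the 2 most abundant IDs in S. carpocapsae, protein-coding genes only, and dauers against males only. The test on counts and the tests on orthologues could not be run, since the tables hold neither. Whether like-numbered replicates belong together was checked from correlations of residuals, and every pair exceeded 0.1 only in C. elegans male against hermaphrodite heads, where the lowest was 0.228 and the highest 0.447.

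The fit was tested on simulated data with 200 changed genes in each of 10 draws. For whole males against hermaphrodites, run on 24134 genes, 33.0% of genes changed by 2 on the log2 scale and 93.6% of those changed by 6 were recovered. For whole males against females, run on 25082 genes, the shares were 8.00% and 92.6%. When simulated values below 0 were set to 0, as in a table of TPM, the share of false calls exceeded the nominal 5%, at 10.6% and 12.5% in these comparisons. It was 29.0% for head against tail in dauers and 19.8% for head against tail in S. carpocapsae males. Without setting values to 0 the shares were 4.87%, 4.00%, 5.20% and 4.15%. Each gene was given the same SD in every group, and changed genes were drawn only from those with a mean level over about 10 TPM. Errors from unequal spread between groups were therefore not tested, and the shares hold for 200 changed genes only. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.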

Results

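PolyA RNA was sequenced from heads, tails and whole bodies of 2 nematodes, the insect parasite Steinernema carpocapsae and the free-living Caenorhabditis elegans, per the labels. Each species gave 27 libraries in 9 groups of 3. The groups were adult males, adult females (hermaphrodites in C. elegans) and the non-feeding larvae that infect or disperse, called infective juveniles (IJs) in S. carpocapsae and dauers in C. elegans, each as head, tail and whole body. The depth of the libraries is unknown, because the deposited values are TPM, the share of transcripts scaled to a fixed total, without read counts, so no counting interval or detection floor is given. Values are mean ± SD in TPM with n = 3 libraries, fold changes are log2 of TPM plus 1, and a group in which every library read 0 is given as listed at 0. Nothing in the labels says whether the 3 replicates of a group came from separate cultures, and groups of 3 were not tested for outliers.

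The dauers were strain N2 starved for 16 weeks at 25 °C, while the C. elegans adults carried him-8(me4), which raises the share of males, and fed on Escherichia coli OP50. Every dauer comparison therefore also compares strain, food and age. The IJs had not been activated, while the S. carpocapsae adults came from worms activated on the symbiotic bacterium Xenorhabdus nematophila.

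In several libraries labelled hermaphrodite, marker genes went against the label. vit-2, a yolk protein gene of the adult hermaphrodite intestine, read 1152 to 1664 TPM in the 3 libraries labelled head but 0.28 to 0.83 TPM in the 3 labelled whole. The adult cuticle collagen col-19 read 195 to 1772 TPM in those heads, below 1 TPM in those whole bodies, and was listed at 0 in all 3 hermaphrodite tails. dpy-13, a cuticle collagen made in larval cycles, read 2353 to 8758 TPM in the hermaphrodite whole libraries, 6202 TPM in hermaphrodite tail replicate 1 and 8557 TPM in male tail replicate 1. rab-3, a synaptic vesicle gene of all neurons, read 0.41 to 1.22 TPM in hermaphrodite heads. Hermaphrodite whole replicate 1 also held male transcripts, with 139 TPM of mab-3 and 320 TPM of cwp-1. The sum of the major sperm proteins read 17037 TPM in male head replicate 1 and 11209 TPM in hermaphrodite head replicate 1. All comparisons keep the labels as given.

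How do whole males differ from whole hermaphrodites of C. elegans? All 29 major sperm proteins were higher in males, and 17 of 18 collagens of the dumpy, roller, blister and squat classes in hermaphrodites. spe-38 (WBGene00013121, chromosome I), a sperm membrane protein needed for fertilization, read 7.17 ± 1.57 TPM in males and was listed at 0 in hermaphrodites (adjusted p = 3.5e-10). peel-1, a toxin carried by sperm, read 75.4 ± 17.8 against 0.357 ± 0.618 TPM (log2 5.88, adjusted p = 1.3e-07). The cuticle collagens sqt-1 and lon-3 went the other way, at 0.460 ± 0.0608 against 9071 ± 1318 TPM (log2 -12.59, adjusted p = 6.4e-08) and 0.0400 ± 0.01 against 1589 ± 304 TPM (log2 -10.56, adjusted p = 1.1e-12). Other collagens were higher in males, among them col-140 at 13730 ± 1297 against 0.233 ± 0.155 TPM (log2 13.45, adjusted p = 1.1e-10). The insulin-like peptide gene ins-31 read 1983 ± 100.4 against 10.7 ± 18.3 TPM (log2 9.18, adjusted p = 9.1e-06).

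Of the major sperm proteins, which drive sperm crawling and signal to oocytes, 29 of 29 were higher, 0 were lower and 0 neither, with the same counts adjusted over the list alone (camera adjusted p = 1.3e-23, but adjusted p = 0.24 with an estimated correlation). Reads may be split among these near-identical copies, of which msp-74 had a log2 fold change of 6.99. Among genes of spermatogenesis and sperm function, 26 of 27 were higher, 0 were lower and 1 neither, with the same counts adjusted over the list alone (camera adjusted p = 5.9e-26, and adjusted p = 0.021 with an estimated correlation). In the cuticle collagens of the dumpy, roller, blister and squat classes, 0 of 18 were higher, 17 were lower and 1 neither, with the same counts adjusted over the list alone (camera adjusted p = 1.6e-14, and adjusted p = 0.018 with an estimated correlation). Genes of the male-specific sensory neurons were mixed, as 4 of 12 were higher, 1 was lower and 7 neither, with the same counts adjusted over the list alone (camera adjusted p = 0.0025, but adjusted p = 0.34 with an estimated correlation). The lower one was tba-9, a tubulin of ciliated neurons, at log2 -1.89 (adjusted p = 0.0079). Without hermaphrodite whole replicate 1, which held male transcripts, tba-9 was at log2 -1.31 (adjusted p = 0.072), and 6 genes of this list were higher and none lower. pkd-2, a polycystin channel of male mating neurons, read 4.84 ± 1.37 against 0.250 ± 0.236 TPM (adjusted p = 0.00045), while lov-1, its partner, had a log2 fold change of 0.06 (adjusted p = 0.93). For the ribosomal proteins, 1 of 78 was higher, 44 were lower and 33 neither, or 1 up and 71 down adjusted over the list alone (camera adjusted p = 2.5e-06, but adjusted p = 0.76 with an estimated correlation), and the median log2 of -1.30 became 0.30 under median-of-ratios scaling. For the histones, 1 of 68 was higher, 35 were lower and 32 neither, or 1 up and 36 down adjusted over the list alone (camera adjusted p = 0.0066, but adjusted p = 0.76 with an estimated correlation). For the cytosolic genes of oxidative phosphorylation, 0 of 33 were higher, 16 were lower and 17 neither, or 23 down adjusted over the list alone (camera adjusted p = 0.00034, but adjusted p = 0.61 with an estimated correlation), and the median log2 of -1.07 became 0.52 under median-of-ratios scaling, with 10 lower without that replicate.

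Few oocyte, eggshell or yolk genes passed the test between the libraries labelled whole. Among the oocyte and eggshell genes, 0 of 20 were higher, 1 was lower and 19 neither, with the same counts adjusted over the list alone (camera adjusted p = 0.29), and the median log2 of -0.02 became 0.87 under median-of-ratios scaling. Of the vitellogenins, 0 of 6 were higher, 0 were lower and 6 neither, with the same counts adjusted over the list alone (camera adjusted p = 0.92). vit-2 had a log2 fold change of -0.52 (adjusted p = 0.52). In the list of sex determination and dosage compensation, 0 of 22 were higher, 11 were lower and 11 neither, or 12 down adjusted over the list alone (camera adjusted p = 0.20), and the median log2 of -1.02 became 0.16 under median-of-ratios scaling. Its members xol-1, her-1 and tra-1 had log2 fold changes of 0.02, 2.08 and -0.59 (adjusted p = 1.0, 0.11 and 0.52), and those of mab-3, myo-2 and rab-3 were 0.93, -0.14 and 1.38 (adjusted p = 0.48, 0.96 and 0.086), where tra-1 and myo-2 changed sign under median-of-ratios scaling. Without hermaphrodite whole replicate 1, mab-3, her-1 and rab-3 passed the test at log2 2.64, 3.60 and 2.37 (adjusted p = 0.00054, 0.0019 and 0.00055), myo-2 changed sign to 0.37, and 3 genes of sex determination and dosage compensation were higher and 7 lower.

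In limma, 2154 genes were higher and 4659 lower in whole males at a false discovery rate of 0.05, and the groups did not overlap in 12163 genes, or 50.4% of those tested, where 10% would be so by chance. Median-of-ratios scaling moved the median of all genes by 0.91 and turned the balance to 2969 higher and 807 lower. Without ribosomal RNA, 2078 were higher and 4245 lower, and the total of 6813 was 11304 with array weights.

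**Figure D1:**
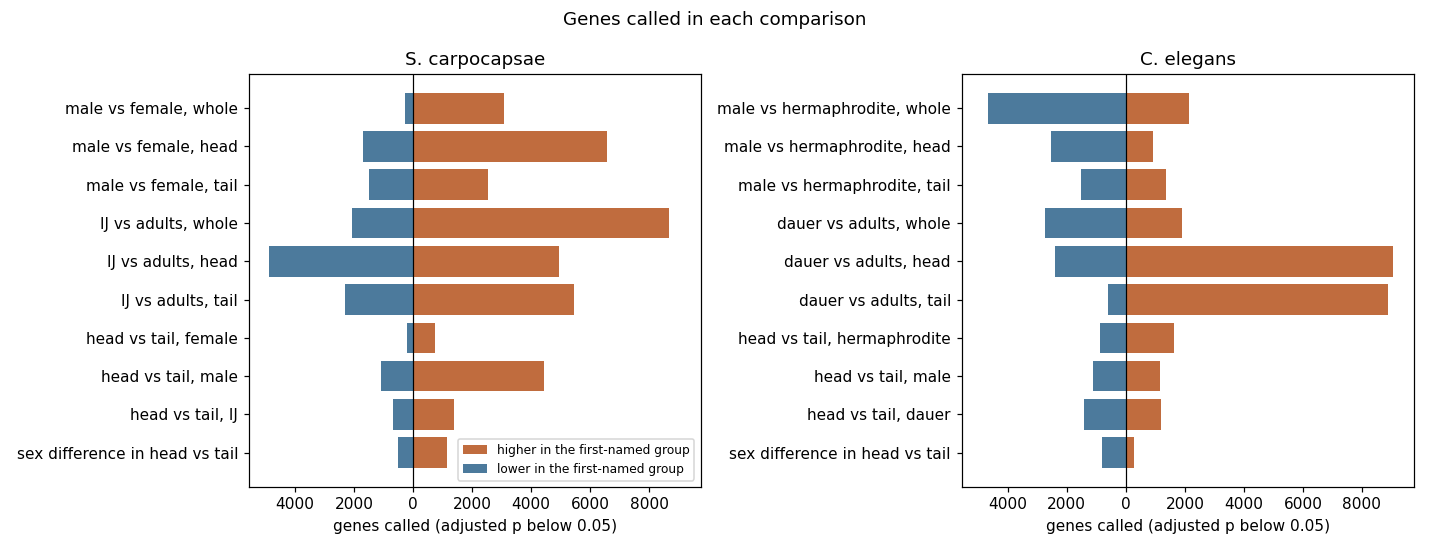
Genes higher and lower in each comparison at a false discovery rate of 0.05, from TPM as deposited. The C. elegans dauer heads had the largest C. elegans count, 9049 higher and 2402 lower.

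How do male heads differ from hermaphrodite heads? 6 of 12 male-specific sensory neuron genes were higher in male heads, and 20 of 20 oocyte and eggshell genes and 6 of 6 vitellogenins in the libraries labelled hermaphrodite head. cwp-1 (WBGene00000859, chromosome V) and cwp-2 (WBGene00000860, chromosome V), made in the male's ciliated CEM neurons, read 645 ± 169.8 and 615 ± 274 TPM in males against 4.77 ± 8.27 and 4.21 ± 4.02 TPM (log2 7.99 and 7.05, adjusted p = 0.00016 and 0.00017). her-1, the secreted signal for male fate, read 237 ± 74.7 against 14.3 ± 7.32 TPM (log2 4.05, adjusted p = 0.0055). The yolk gene vit-6 read 0.383 ± 0.126 TPM in male and 1897 ± 129.8 TPM in hermaphrodite heads (log2 -10.42, adjusted p = 3.9e-14), and vit-2 0.387 ± 0.359 and 1376 ± 262 TPM (log2 -9.97, adjusted p = 4.5e-12). cpg-1, an eggshell proteoglycan, read 0.633 ± 0.405 against 597 ± 130 TPM (log2 -8.52, adjusted p = 1.1e-09), and pcn-1, the replication clamp, had a log2 fold change of -5.61 (adjusted p = 1.1e-06).

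Of the oocyte and eggshell genes, 0 of 20 were higher, 20 were lower and 0 neither, with the same counts adjusted over the list alone (camera adjusted p = 5.7e-36, and adjusted p = 0.018 with an estimated correlation), and of the vitellogenins, 0 of 6 were higher, 6 were lower and 0 neither, with the same counts adjusted over the list alone (camera adjusted p = 4.3e-21, and adjusted p = 0.0016 with an estimated correlation). For germ line and meiosis, 0 of 21 were higher, 17 were lower and 4 neither, or 19 down adjusted over the list alone (camera adjusted p = 2.4e-12, but adjusted p = 0.31 with an estimated correlation). For DNA replication and mitosis, 0 of 20 were higher, 20 were lower and 0 neither, with the same counts adjusted over the list alone (camera adjusted p = 1.0e-25, but adjusted p = 0.058 with an estimated correlation). On the male side, among the male-specific sensory neuron genes 6 of 12 were higher, 0 were lower and 6 neither, or 8 up adjusted over the list alone (camera adjusted p = 1.3e-06, but adjusted p = 0.12 with an estimated correlation). pkd-2 read 6.59 ± 1.24 TPM in male heads and was listed at 0 in hermaphrodite heads (adjusted p = 6.5e-05). Of the pan-neuronal genes, 10 of 15 were higher, 0 were lower and 5 neither, or 11 up adjusted over the list alone (camera adjusted p = 1.5e-07, but adjusted p = 0.30 with an estimated correlation), with rab-3 at 7.44 ± 1.19 against 0.730 ± 0.431 TPM (adjusted p = 0.0099). Among the FMRFamide-like peptides, which are neuropeptides, 7 of 31 were higher, 0 were lower and 24 neither, or 10 up adjusted over the list alone (camera adjusted p = 8.2e-08, but adjusted p = 0.46 with an estimated correlation). Insulin-like peptide genes followed, as 11 of 38 were higher, 2 were lower and 25 neither, or 14 up and 2 down adjusted over the list alone (camera adjusted p = 7.3e-05, but adjusted p = 0.12 with an estimated correlation), with ins-39, a peptide of a chemosensory neuron, at 212 ± 144 against 1.79 ± 2.06 TPM (log2 6.29, adjusted p = 0.00030). Of the pharynx genes, 4 of 14 were higher, 0 were lower and 10 neither, or 6 up adjusted over the list alone (camera adjusted p = 0.00080, but adjusted p = 0.36 with an estimated correlation), and myo-2, the pharyngeal muscle myosin, read 62.4 ± 28.6 against 6.93 ± 2.82 TPM (adjusted p = 0.019). For the ribosomal proteins, 0 of 78 were higher, 11 were lower and 67 neither, or 37 down adjusted over the list alone (camera adjusted p = 1.4e-13, but adjusted p = 0.57 with an estimated correlation). mab-3, a transcription factor of male differentiation, had a log2 fold change of 3.41 (adjusted p = 0.0088), and lov-1, xol-1 and tra-1 of 0.16, 0.27 and 1.53 (adjusted p = 0.97, 0.84 and 0.085).

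In limma, 929 genes were higher and 2548 lower in male heads, and the groups did not overlap in 9302 genes (38.5%, with 10% by chance). The total of 3477 was 2136 without male head replicate 1, 2216 without hermaphrodite head replicate 2 and 2217 without male head replicate 2, 5584 with only the 6 libraries compared and 8403 with array weights. Median-of-ratios scaling moved the median of all genes by 0.13 and gave 2224 higher and 2729 lower. A replicate term over all 27 libraries gave 3358. Only here did every like-numbered pair correlate above 0.1, but no paired fit was run.

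How do male tails, which carry the copulatory organ, differ from hermaphrodite tails? 9 of 12 male-specific sensory neuron genes and 10 of 19 neurotransmitter genes were higher in male tails. tdc-1 (WBGene00006562, chromosome II), tyrosine decarboxylase of tyramine and octopamine synthesis, read 404 ± 235.0 against 1.68 ± 1.79 TPM (log2 7.27, adjusted p = 9.9e-07). cat-1, the vesicular monoamine transporter, read 42.4 ± 11.9 against 1.10 ± 1.29 TPM (log2 4.51, adjusted p = 2.4e-05). pkd-2 read 15.6 ± 2.01 against 0.113 ± 0.115 TPM (log2 3.90, adjusted p = 1.7e-06), and cwp-1 read 670 ± 184 TPM while listed at 0 in hermaphrodites (adjusted p = 3.5e-05). The male tail fate genes mab-3 and mab-23 had log2 fold changes of 4.79 and 4.99 (adjusted p = 0.00055 and 0.00010). fipr-17, of a family related to fungus-induced proteins, read 18160 ± 6464 TPM in male tails and was listed at 0 in hermaphrodite tails (adjusted p = 2.4e-06).

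Among the male-specific sensory neuron genes, 9 of 12 were higher, 0 were lower and 3 neither, or 11 up adjusted over the list alone (camera adjusted p = 9.2e-13, and adjusted p = 0.018 with an estimated correlation). For neurotransmitter synthesis and transport, 10 of 19 were higher, 0 were lower and 9 neither, or 14 up adjusted over the list alone (camera adjusted p = 8.9e-10, but adjusted p = 0.24 with an estimated correlation). Of the FMRFamide-like peptides, 9 of 31 were higher, 0 were lower and 22 neither, or 15 up adjusted over the list alone (camera adjusted p = 4.8e-09, but adjusted p = 0.41 with an estimated correlation). Of the pan-neuronal genes, 4 of 15 were higher, 0 were lower and 11 neither, or 11 up adjusted over the list alone (camera adjusted p = 2.7e-06, but adjusted p = 0.34 with an estimated correlation), with rab-3 at 148 ± 42.9 against 1.70 ± 1.499 TPM (log2 5.96, adjusted p = 2.4e-07). For body wall muscle, 3 of 13 were higher, 0 were lower and 10 neither, or 5 up adjusted over the list alone (camera adjusted p = 0.00020, but adjusted p = 0.37 with an estimated correlation). On the hermaphrodite side, 0 of 78 were higher, 76 were lower and 2 neither, or 77 down adjusted over the list alone (camera adjusted p = 5.1e-67, but adjusted p = 0.12 with an estimated correlation) among the ribosomal proteins. nucl-1, a nucleolin, and nol-58, a nucleolar protein, had log2 fold changes of -5.34 and -5.36 (adjusted p = 0.00017 and 0.00023). For oxidative phosphorylation, 0 of 33 were higher, 12 were lower and 21 neither, or 18 down adjusted over the list alone (camera adjusted p = 1.3e-09, but adjusted p = 0.35 with an estimated correlation). In DNA replication and mitosis, 0 of 20 were higher, 11 were lower and 9 neither, or 14 down adjusted over the list alone (camera adjusted p = 1.3e-09, but adjusted p = 0.31 with an estimated correlation). The fixed genes her-1 and lov-1 had log2 fold changes of 4.13 and 1.38 (adjusted p = 0.0053 and 0.0020), and vit-2, xol-1, tra-1 and myo-2 of -0.11, 0.60, 0.73 and -0.10 (adjusted p = 1.0, 0.30, 0.55 and 1.0), where vit-2 changed sign under median-of-ratios scaling.

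In limma, 1368 genes were higher and 1522 lower in male tails, and the groups did not overlap in 4924 genes (20.4%, with 10% by chance). Under median-of-ratios scaling the median of all genes moved by 0.37 and the counts became 2953 higher and 893 lower, and removing ribosomal RNA gave 1066 and 1945. The total of 2890 was 287 with only the 6 libraries compared and 7984 with array weights. Hermaphrodite tail replicate 1 held 7442 genes at 1 TPM or more, its posterior Hox genes egl-5, php-3 and nob-1 were listed at 0 (mean log2 2.39 and 2.49 in the other two), and 5 of 16 pan-neuronal genes were above 0 (mean log2 0.695 against 2.54 and 3.19).

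How do whole dauers differ from the mean of whole males and hermaphrodites? In dauers 13 of 25 ciliated sensory neuron genes rose, and all 29 major sperm proteins fell. daf-7 (WBGene00000903, chromosome III), the TGF-beta ligand that prevents dauer entry, read 159 ± 55.5 TPM in dauers, 5.48 ± 2.54 in males and 45.7 ± 38.7 in hermaphrodites (log2 3.40, adjusted p = 0.00042). Its receptor daf-4 and the FOXO factor daf-16 had log2 fold changes of 2.39 and 1.41 (adjusted p = 9.7e-05 and 0.0055). The metallothionein mtl-1 and the invertebrate lysozyme ilys-3 rose by log2 4.33 and 8.65 (adjusted p = 0.017 and 0.0027). tag-293 read 2490 ± 430.5 TPM against 27.2 ± 27.5 and 1.74 ± 2.18 in males and hermaphrodites (log2 8.51, adjusted p = 1.7e-07). dod-24, a gene downstream of daf-16, had a log2 fold change of -8.20 (adjusted p = 2.0e-06).

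Of the ciliated sensory neuron genes, 13 of 25 rose, 0 fell and 12 did neither, or 14 up adjusted over the list alone (camera adjusted p = 1.1e-07, but adjusted p = 0.24 with an estimated correlation), including odr-10, the diacetyl receptor, at log2 2.59 (adjusted p = 6.0e-05). Of the FMRFamide-like peptides, 11 of 31 rose, 1 fell and 19 did neither, or 15 up and 1 down adjusted over the list alone (camera adjusted p = 5.2e-08, but adjusted p = 0.45 with an estimated correlation), with flp-1 at 1127 ± 178 TPM in dauers. In the dauer signalling pathway, 6 of 16 rose, 0 fell and 10 did neither, or 10 up adjusted over the list alone (camera adjusted p = 7.7e-05, but adjusted p = 0.15 with an estimated correlation). For stress protection and glyoxylate or trehalose metabolism, 6 of 19 rose, 1 fell and 12 did neither, or 7 up and 1 down adjusted over the list alone (camera adjusted p = 0.015, but adjusted p = 0.56 with an estimated correlation). Of the pharynx genes, 6 of 14 rose, 2 fell and 6 did neither, or 10 up and 2 down adjusted over the list alone (camera adjusted p = 0.0072, but adjusted p = 0.49 with an estimated correlation). On the falling side, among the major sperm proteins 0 of 29 rose, 29 fell and 0 did neither, with the same counts adjusted over the list alone (camera adjusted p = 4.0e-15, but adjusted p = 0.34 with an estimated correlation), and among the other sperm genes 0 of 27 rose, 23 fell and 4 did neither, or 27 down adjusted over the list alone (camera adjusted p = 7.2e-16, but adjusted p = 0.091 with an estimated correlation). The mean sum of the major sperm proteins was 112041 TPM in males, 181.02 TPM in hermaphrodites and 4.57 TPM in dauers. For the collagens of the dumpy, roller, blister and squat classes, 0 of 18 rose, 14 fell and 4 did neither, or 16 down adjusted over the list alone (camera adjusted p = 1.5e-14, and adjusted p = 0.018 with an estimated correlation). None of these collagens fell against males only, and their mean log2 level was 0.394 in dauers, 0.719 in males and 8.95 in hermaphrodites. In DNA replication and mitosis, 0 of 20 rose, 5 fell and 15 did neither, or 6 down adjusted over the list alone (camera adjusted p = 0.00028, but adjusted p = 0.57 with an estimated correlation). Against males only 3 of these genes fell, with a median log2 of -0.39 in place of -1.07.

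In limma, 1891 genes rose and 2732 fell in whole dauers, of 4623 in all. Ribosomal RNA took 41.9% of TPM in whole dauers, 4.26% in hermaphrodites and 2.82% in males, and without it 4336 genes rose and 2319 fell. Median-of-ratios scaling moved the median of all genes by -0.19 and gave 1685 and 3604, and against males only 3464 rose and 2422 fell.

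How do dauer heads differ from adult heads? In dauer heads 25 of 25 ciliated sensory neuron genes rose, and 73 of 78 ribosomal protein genes fell. odr-10 (WBGene00003856, chromosome X) read 16.52 ± 5.80 TPM in dauer heads against 0.513 ± 0.536 in males and 0.597 ± 0.276 in hermaphrodites (log2 3.48, adjusted p = 5.4e-07). daf-12, the nuclear receptor that decides between dauer and growth, read 31.6 ± 4.05 against 2.01 ± 0.609 and 0.507 ± 0.284 TPM (log2 3.95, adjusted p = 4.2e-06). sod-5, a superoxide dismutase, read 629 ± 318 against 0.260 ± 0.450 and 0.210 ± 0.104 TPM (log2 8.91, adjusted p = 4.5e-11). lys-1, a lysozyme, and asp-1, an intestinal aspartic protease, read 3.95 ± 1.55 and 4.44 ± 4.43 TPM in dauers against 854 ± 342 and 2778 ± 728 TPM in males (log2 -6.72 and -8.62, adjusted p = 1.4e-07 and 6.4e-06). The insulin-like genes daf-28 and ins-7 had log2 fold changes of -3.42 and -4.32 (adjusted p = 1.3e-06 and 2.0e-06).

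Of the ciliated sensory neuron genes, 25 of 25 rose, 0 fell and 0 did neither, with the same counts adjusted over the list alone (camera adjusted p = 2.1e-07, but adjusted p = 0.25 with an estimated correlation). Among the ribosomal proteins, 0 of 78 rose, 73 fell and 5 did neither, or 75 down adjusted over the list alone (camera adjusted p = 5.6e-39, but adjusted p = 0.25 with an estimated correlation). Against males only 50 of them fell and 1 rose, with a median log2 of -1.38 in place of -1.96. For oxidative phosphorylation, 1 of 33 rose, 25 fell and 7 did neither, or 1 up and 26 down adjusted over the list alone (camera adjusted p = 1.3e-22, but adjusted p = 0.12 with an estimated correlation), with cox-6B, a subunit of cytochrome c oxidase, at log2 -2.85 (adjusted p = 4.5e-07). Of the antimicrobial and lysozyme genes, 2 of 19 rose, 12 fell and 5 did neither, with the same counts adjusted over the list alone (camera adjusted p = 8.0e-08, but adjusted p = 0.15 with an estimated correlation). Of the intestine genes, 1 of 13 rose, 8 fell and 4 did neither, or 2 up and 8 down adjusted over the list alone (camera adjusted p = 4.4e-05, but adjusted p = 0.12 with an estimated correlation). For the vitellogenins, 0 of 6 rose, 5 fell and 1 did neither, or 6 down adjusted over the list alone (camera adjusted p = 4.0e-07, but adjusted p = 0.090 with an estimated correlation). In DNA replication and mitosis, 0 of 20 rose, 12 fell and 8 did neither, with the same counts adjusted over the list alone (camera adjusted p = 4.2e-08, but adjusted p = 0.34 with an estimated correlation). Against males only no gene of these 2 lists fell, and 4 vitellogenins and 2 genes of DNA replication and mitosis rose. In the dauer signalling pathway, 10 of 16 rose, 2 fell and 4 did neither, with the same counts adjusted over the list alone (camera adjusted p = 0.46), and of the pan-neuronal genes, 11 of 15 rose, 0 fell and 4 did neither, or 12 up adjusted over the list alone (camera adjusted p = 0.13), of which 1 rose against males only.

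In limma, 9049 genes rose and 2402 fell in dauer heads, and against males only 7310 and 1466. Dauer heads held 17963 to 19926 genes at 1 TPM or more, against 11772 to 12211 in whole dauers. Ribosomal RNA took 60.6% of TPM in dauer and 15.4% in male heads. Without it 14545 rose and 1039 fell, so it may add to the list falls above.

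How do dauer tails differ from adult tails? The stress genes sod-5, mtl-1 and sod-3 rose in dauer tails, and 21 of 68 histone genes fell. sod-5 (WBGene00007036, chromosome II) read 106 ± 115 TPM in dauer tails against 1.02 ± 1.16 in males and 0.250 ± 0.433 in hermaphrodites (log2 5.63, adjusted p = 1.0e-07). mtl-1, the superoxide dismutase sod-3 and daf-16 rose by log2 7.25, 4.60 and 2.18 (adjusted p = 0.00015, 0.00014 and 6.5e-05). The collagen col-93, the proteoglycan gene cpg-9 and tdc-1 had log2 fold changes of -9.28, -6.81 and -3.70 (adjusted p = 0.00044, 1.0e-06 and 0.00027). For tdc-1 only males raised the adult mean.

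Of the histones, 1 of 68 rose, 21 fell and 46 did neither, with the same counts adjusted over the list alone (camera adjusted p = 1.1e-23, but adjusted p = 0.12 with an estimated correlation). Among the small heat shock proteins, 3 of 12 rose, 5 fell and 4 did neither, with the same counts adjusted over the list alone (camera adjusted p = 4.2e-06, but adjusted p = 0.12 with an estimated correlation), of which none rose against males only, with the near-identical hsp-16.1 and hsp-16.48, between which reads may be split, at -4.44 and -5.14 (adjusted p = 7.4e-05 and 2.7e-05). For stress protection and glyoxylate or trehalose metabolism, 11 of 19 rose, 1 fell and 7 did neither, with the same counts adjusted over the list alone (camera adjusted p = 0.35). Of the mitochondrially encoded transcripts, 10 of 12 rose, 0 fell and 2 did neither, with the same counts adjusted over the list alone (camera adjusted p = 0.039, but adjusted p = 0.76 with an estimated correlation). In the dauer signalling pathway, 8 of 16 rose, 0 fell and 8 did neither, with the same counts adjusted over the list alone (camera adjusted p = 0.23), and of the insulin-like peptides, 12 of 38 rose, 0 fell and 26 did neither, with the same counts adjusted over the list alone (camera adjusted p = 0.68).

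In limma, 8872 genes rose and 618 fell in dauer tails, and against males only 8150 rose and 975 fell. Scaling by the median of ratios moved the median of all genes by -0.43 and gave 5498 and 1200, and the total of 9490 was 3160 with only the 9 libraries compared and 2906 with array weights. The 3 dauer tails correlated at 0.573 to 0.692 with each other, and replicate 3 held 26.2 TPM of myo-2 against 0.40 and 0.49 TPM in the other two.

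Which genes separate the head from the tail of hermaphrodites? In the head 9 of 14 pharynx genes and 19 of 20 oocyte and eggshell genes were higher. phat-6 (WBGene00011683, chromosome X), a pharyngeal gland gene, read 112.9 ± 66.7 TPM in heads and 0.0300 ± 0.0520 TPM in tails (log2 6.64, adjusted p = 3.1e-08). flp-1, a neuropeptide gene of head interneurons, read 376 ± 189 and 0.590 ± 1.02 TPM (log2 7.96, adjusted p = 3.7e-10). The eggshell gene perm-2 read 3907 ± 1760 and 0.327 ± 0.412 TPM (log2 11.47, adjusted p = 4.2e-12). Collagens stood at both ends, with col-140 at 12.37 and col-107 at -9.10 (adjusted p = 3.5e-10 and 0.0023). ifb-2, an intestinal intermediate filament, had a log2 fold change of -2.96 (adjusted p = 0.0017).

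Of the pharynx genes, 9 of 14 were higher, 0 were lower and 5 neither, or 10 up adjusted over the list alone (camera adjusted p = 1.0e-09, but adjusted p = 0.090 with an estimated correlation). Among the insulin-like peptides, 19 of 38 were higher, 0 were lower and 19 neither, or 20 up adjusted over the list alone (camera adjusted p = 1.9e-15, and adjusted p = 0.0021 with an estimated correlation), and among the FMRFamide-like peptides, 15 of 31 were higher, 0 were lower and 16 neither, or 18 up adjusted over the list alone (camera adjusted p = 1.7e-11, but adjusted p = 0.34 with an estimated correlation). For the oocyte and eggshell genes, 19 of 20 were higher, 0 were lower and 1 neither, with the same counts adjusted over the list alone (camera adjusted p = 5.5e-32, and adjusted p = 0.021 with an estimated correlation), and for the vitellogenins, 6 of 6 were higher, 0 were lower and 0 neither, with the same counts adjusted over the list alone (camera adjusted p = 2.5e-23, and adjusted p = 0.0011 with an estimated correlation). In DNA replication and mitosis, 8 of 20 were higher, 0 were lower and 12 neither, or 17 up adjusted over the list alone (camera adjusted p = 6.7e-11, but adjusted p = 0.27 with an estimated correlation). Of the mitochondrially encoded transcripts, 0 of 12 were higher, 7 were lower and 5 neither, or 8 down adjusted over the list alone (camera adjusted p = 1.2e-07, but adjusted p = 0.31 with an estimated correlation). In limma, 1615 genes were higher in the head and 883 in the tail. The total of 2498 was 1654 without hermaphrodite head replicate 2, 651 with only the 6 libraries compared and 6422 with array weights. Under median-of-ratios scaling the median of all genes moved by 0.17 and the counts became 2784 and 712, and removing ribosomal RNA gave 1250 and 1122.

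Which genes separate the head from the tail of males? In the head 10 of 14 pharynx genes were higher, and in the tail tdc-1 and 33 of 68 histone genes. phat-8 (WBGene00008841, chromosome II), a pharyngeal gland gene, read 4540 ± 859.5 TPM in heads and 0.140 ± 0.242 TPM in tails (log2 11.96, adjusted p = 1.9e-13). fip-2, a fungus-induced protein gene, read 6583 ± 2342 and 0.457 ± 0.205 TPM (log2 12.08, adjusted p = 5.3e-15). flp-1 read 901 ± 411 TPM in heads and was listed at 0 in tails (adjusted p = 4.2e-11). tdc-1 read 2.17 ± 0.788 TPM in heads and 404 ± 235.0 TPM in tails (log2 -6.80, adjusted p = 1.7e-06), and cat-1 had a log2 fold change of -3.96 (adjusted p = 8.8e-05).

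Of the pharynx genes, 10 of 14 were higher, 0 were lower and 4 neither, with the same counts adjusted over the list alone (camera adjusted p = 5.1e-17, and adjusted p = 0.018 with an estimated correlation). Among the insulin-like peptides, 22 of 38 were higher, 0 were lower and 16 neither, or 24 up and 3 down adjusted over the list alone (camera adjusted p = 2.4e-19, and adjusted p = 0.0011 with an estimated correlation). For neurotransmitter synthesis and transport, 0 of 19 were higher, 7 were lower and 12 neither, or 9 down adjusted over the list alone (camera adjusted p = 3.5e-06, but adjusted p = 0.36 with an estimated correlation). Of the histones, 0 of 68 were higher, 33 were lower and 35 neither, or 1 up and 42 down adjusted over the list alone (camera adjusted p = 1.8e-16, but adjusted p = 0.23 with an estimated correlation). Ribosomal proteins went with the head, as 48 of 78 were higher, 0 were lower and 30 neither, or 69 up adjusted over the list alone (camera adjusted p = 1.5e-30, but adjusted p = 0.31 with an estimated correlation), and for oxidative phosphorylation, 16 of 33 were higher, 0 were lower and 17 neither, or 21 up adjusted over the list alone (camera adjusted p = 1.9e-13, but adjusted p = 0.27 with an estimated correlation). Ribosomal RNA took 15.4% of TPM in male heads and 0.551% in male tails. In limma, 1160 genes were higher in the head and 1103 in the tail. The total of 2263 was 1465 without male head replicate 1 and 5799 with array weights. Scaling by the median of ratios moved the median of all genes by -0.07 and turned the balance to 1441 and 1731.

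Which genes separate the head from the tail of dauers? In the head 8 of 14 pharynx genes were higher, and in the tail 65 of 78 ribosomal protein genes. flp-1 (WBGene00001444, chromosome IV) read 1605 ± 279.7 TPM in heads and 1.86 ± 1.97 TPM in tails (log2 9.32, adjusted p = 2.7e-10). myo-2 and odr-10 had log2 fold changes of 5.42 and 2.90 (adjusted p = 0.00016 and 0.00015). asp-1 and the neuropeptide gene nlp-17 were lower in the head, at log2 -8.64 and -8.77 (adjusted p = 0.00020 and 0.00047).

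Of the pharynx genes, 8 of 14 were higher, 0 were lower and 6 neither, or 9 up adjusted over the list alone (camera adjusted p = 1.6e-10, but adjusted p = 0.074 with an estimated correlation). Among the insulin-like peptides, 11 of 38 were higher, 1 was lower and 26 neither, or 12 up and 1 down adjusted over the list alone (camera adjusted p = 1.4e-06, but adjusted p = 0.064 with an estimated correlation). For the ciliated sensory neuron genes, 10 of 25 were higher, 0 were lower and 15 neither, or 12 up adjusted over the list alone (camera adjusted p = 1.6e-09, but adjusted p = 0.15 with an estimated correlation). Of the ribosomal proteins, 0 of 78 were higher, 65 were lower and 13 neither, or 74 down adjusted over the list alone (camera adjusted p = 2.8e-30, but adjusted p = 0.31 with an estimated correlation). Of the intestine genes, 0 of 13 were higher, 6 were lower and 7 neither, or 7 down adjusted over the list alone (camera adjusted p = 0.00011, but adjusted p = 0.15 with an estimated correlation). In limma, 1198 genes were higher in the head and 1427 in the tail, of 2625 in all. The total was 43 with only the 6 libraries compared, 1574 with a pseudocount of 0.1 and 340 with array weights, and in simulated data with values below 0 set to 0 29% of the calls were false. Median-of-ratios scaling moved the median of all genes by 0.43 and gave 2228 and 624, and removing ribosomal RNA gave 3795 and 700. Ribosomal RNA took 60.6% of TPM in dauer heads and 25.5% in dauer tails.

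**Figure D2:**
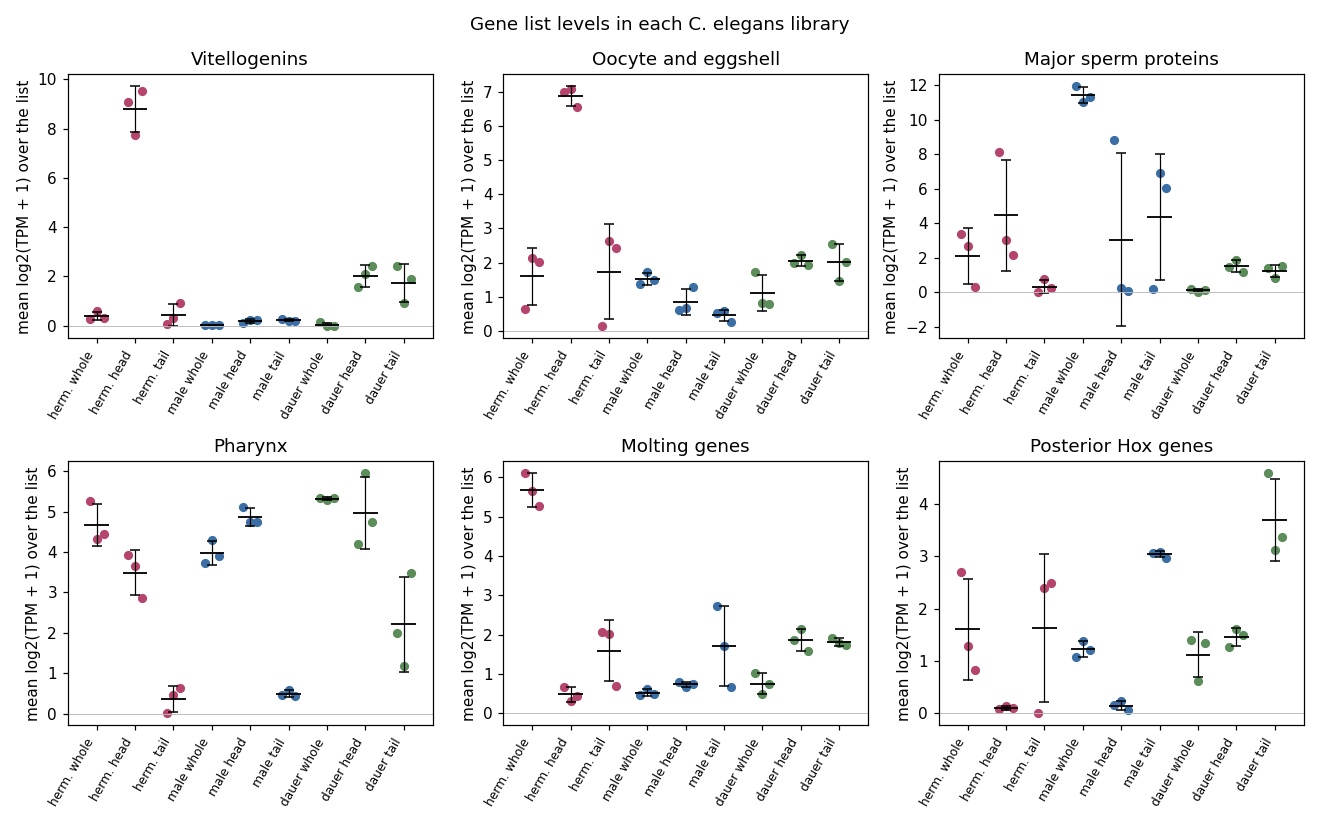
Mean log2 level of gene lists in each C. elegans library. The pharynx genes had a mean log2 level of 4.86 in male heads and 0.49 in male tails.

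Did the difference between head and tail depend on sex in C. elegans? In males 6 of 6 vitellogenins and 15 of 20 oocyte and eggshell genes had a lower head-to-tail difference. vit-6 read 1897 ± 129.8 TPM in hermaphrodite heads and 0.387 ± 0.644 TPM in hermaphrodite tails, against 0.383 ± 0.126 TPM in male heads. Of the vitellogenins, 0 of 6 were higher, 6 were lower and 0 neither, with the same counts adjusted over the list alone (camera adjusted p = 4.5e-24, and adjusted p = 0.0011 with an estimated correlation), and of the oocyte and eggshell genes, 0 of 20 were higher, 15 were lower and 5 neither, or 19 down adjusted over the list alone (camera adjusted p = 6.2e-27, and adjusted p = 0.042 with an estimated correlation). Among the ribosomal proteins, 7 of 78 were higher, 0 were lower and 71 neither, or 68 up adjusted over the list alone (camera adjusted p = 2.8e-30, but adjusted p = 0.31 with an estimated correlation). Of the histones, 0 of 68 were higher, 16 were lower and 52 neither, or 1 up and 26 down adjusted over the list alone (camera adjusted p = 1.5e-14, but adjusted p = 0.26 with an estimated correlation). For the cytosolic oxidative phosphorylation genes, 7 of 33 were higher, 0 were lower and 26 neither, or 25 up adjusted over the list alone (camera adjusted p = 1.1e-17, but adjusted p = 0.18 with an estimated correlation), and for the mitochondrially encoded transcripts, 7 of 12 were higher, 0 were lower and 5 neither, or 10 up adjusted over the list alone (camera adjusted p = 1.0e-09, but adjusted p = 0.25 with an estimated correlation). The fungus-induced relative fipr-17 had an interaction of -14.90 log2, and the cathepsin B gene cpr-4 of 6.83 (adjusted p = 0.00013 and 0.047). In limma, 268 genes had a higher and 821 a lower difference in males. Scaling by the median of ratios moved the median of all genes by -0.26 and gave 279 and 1571, and removing ribosomal RNA gave 564 and 653. The total of 1089 was 4740 with array weights.

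The S. carpocapsae table lists its genes under IDs that the sources used here do not pair with names, so at most 2 IDs of each direction are given and no gene list was tested. How do male and female S. carpocapsae differ? In whole bodies, g8775 read 13720 ± 4190 TPM in males and 0.710 ± 0.906 TPM in females (log2 13.05, adjusted p = 2.0e-08), and g9126 read 11240 ± 3099 and 0.233 ± 0.404 TPM (log2 13.16, adjusted p = 7.1e-09). g28734 read 2.21 ± 2.49 TPM in males and 95760 ± 92040 TPM in females (log2 -14.30, adjusted p = 2.2e-06), and g28755 had a log2 fold change of -12.39 (adjusted p = 1.2e-07). Both genes were higher in male tails too, with g8775 at 18520 ± 18300 TPM and g9126 at 14740 ± 15150 TPM, each listed at 0 in female tails (adjusted p = 2.7e-07 and 2.0e-07). g4835 and g24318 were lower in male tails, at 3.76 ± 3.36 against 2204 ± 384 TPM and 0.143 ± 0.248 against 499.9 ± 297 TPM (log2 -9.28 and -8.64, adjusted p = 1.1e-07 and 0.00016). In heads, g26124 read 20310 ± 10940 TPM in males and 8.12 ± 12.5 TPM in females (log2 12.01, adjusted p = 1.0e-08), and g26125 had a log2 fold change of 11.45 (adjusted p = 3.7e-08). g19938 read 11.3 ± 4.44 and 7106 ± 946 TPM (log2 -9.23, adjusted p = 1.3e-07). Of the genes higher in males, 1741 were shared between whole bodies and tails, where independence of the calls would give 315.9.

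In limma, 3096 genes were higher and 274 lower in whole males, 6579 and 1708 in male heads, and 2559 and 1499 in male tails, and the groups did not overlap in 22.04%, 44.2% and 47.1% of genes, where 10% would be so by chance. Median-of-ratios scaling moved the medians of all genes by -0.35, 0.11 and 0.41, and gave 3410 and 953 in whole bodies, 8616 and 2183 in heads and 8312 and 2098 in tails. The 2 most abundant IDs took 40.02% of TPM in male heads and 1.90% in female heads, and without them 9684 genes were higher and 983 lower in male heads. The male heads held 17989 to 23564 genes at 1 TPM or more, 15042 to 17091 of them under 10 TPM, against 9715 to 13245 genes in female heads, and male head replicate 3 correlated at 0.594 and 0.610 with its own group but at 0.803 with male tail replicate 1. The whole-body total of 3370 was 5302 without male whole replicate 1 and 5655 without female whole replicate 3, 1994 with only the 6 libraries compared and 18887 with array weights. The tail total of 4058 was 2543 without male tail replicate 2, 8126 with only the 6 libraries compared, 6232 with a pseudocount of 0.1 and 7921 with array weights.

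How do IJs of S. carpocapsae differ from adults? g593 read 2765 ± 313 TPM in whole IJs against 0.0533 ± 0.0924 in males and 0.0600 ± 0.104 in females (log2 11.35, adjusted p = 3.6e-11), and 12360 ± 5569 TPM in IJ tails (log2 13.37, adjusted p = 1.6e-12). g594 rose by log2 9.85 in whole bodies (adjusted p = 8.4e-13). In IJ heads, g23209 read 11810 ± 4797 TPM against 1.53 ± 0.399 and 3.25 ± 1.06 TPM (log2 11.74, adjusted p = 3.6e-15). g29613 and g5706 had log2 fold changes of -11.08 and -10.83 in whole bodies (adjusted p = 6.2e-12 and 1.7e-11) and were both listed at 0 in IJ heads (adjusted p = 3.0e-13 and 2.9e-13). In limma, 8679 genes rose and 2080 fell in whole IJs, 4937 and 4869 in heads and 5460 and 2298 in tails. Median-of-ratios scaling moved the medians of all genes by -1.02, -0.47 and -0.79 and turned the balance to 3466 and 4782, 3223 and 7122, and 3130 and 6900. Without the 2 most abundant IDs, 10657 and 1615, 5003 and 5905, and 6029 and 2106 rose and fell.

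Which genes separate head from tail in S. carpocapsae, and did this depend on sex? In females, g10165 read 3358 ± 381 TPM in heads and 0.387 ± 0.223 TPM in tails (log2 11.25, adjusted p = 6.6e-08), and g5968 read 0.05 ± 0.0866 and 3101 ± 609 TPM (log2 -11.51, adjusted p = 1.6e-08). In males, g28522 was higher in heads by log2 7.74 (adjusted p = 8.7e-05), while g8775 read 151 ± 261 TPM in heads and 18520 ± 18300 TPM in tails (log2 -10.63, adjusted p = 8.2e-06). In IJs, g10334 read 5683 ± 4120 and 0.05 ± 0.0866 TPM (log2 12.16, adjusted p = 7.9e-09), and g3565 had a log2 fold change of -8.77 (adjusted p = 3.4e-07). The head-to-tail difference of g24318 was higher in males by log2 11.06 and that of g8775 lower, at -10.63 (adjusted p = 0.0031 and 0.0017).

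In limma, 755 genes were higher in heads and 210 in tails of females, 4429 and 1099 in males and 1388 and 680 in IJs, and 1151 had a higher and 503 a lower difference in males. Median-of-ratios scaling moved the medians of all genes by -0.22, -0.60 and -0.31 in females, males and the interaction, and gave 769 and 401, 2169 and 2142, and 541 and 786. Without the 2 most abundant IDs, 8116 and 1001 genes were higher and lower in male heads and 2162 and 416 in the interaction. The female total of 965 was 568 without female head replicate 2, 576 without female head replicate 3, 591 without female tail replicate 1 and 608 without female tail replicate 3, 615 with only the 6 libraries compared and 11114 with array weights. For the male total of 5528, limma with only the 6 libraries compared called 0 genes, with 8072 at an unadjusted p under 0.05, the total was 2810 with a pseudocount of 0.1, and the IJ total of 2068 became 153. The interaction total of 1654 was 968 without female tail replicate 1, 1014 without female head replicate 3, 1041 without female tail replicate 2, 1047 without female tail replicate 3 and 1101 without male tail replicate 2, 229 with a pseudocount of 0.1 and 5252 with array weights.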

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

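The tests of male transcripts in hermaphrodite whole replicate 1, the dilution test of dauer heads and the test of scattered reads in dauer tails were chosen only after the result was seen. The difference between head and tail that depends on sex was what brought the following results to attention. In S. carpocapsae, 1654 genes were called in this interaction. In 13 of 100 splits of the libraries, counting the real grouping, as many or more were called, with 4951 as the highest of the others. Among the genes called, g24318 and g24317 had interactions of 11.06 and 8.79, and g8775 and g9126 of -10.63 and -9.997. In C. elegans, 1089 genes were called. There 4 of 100 splits, counting the real grouping, gave as many or more, a share under 0.05, with 3598 as the highest of the others. These splits exchanged the sexes separately within heads and within tails, which can turn a sex difference into an apparent interaction. Neither share therefore measures chance for the interaction, and chance was not excluded in either species.

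The C. elegans genes with the largest interactions were rrn-3.1 and rrn-1.1, ribosomal RNA genes, at 8.59 and 7.08, the latter equal for its 2 IDs, and cpr-4 at 6.83. On the negative side stood fipr-20, fipr-17, fipr-18 and K02B12.6, at -14.94, -14.90, -13.51 and -13.49. For gene lists, the median is followed by the genes called of those tested and by the adjusted p of camera with the preset and with an estimated correlation. Medians under 0 were -6.26 for major sperm proteins (0 of 29, adjusted p = 8.0e-08 and 0.57), -4.14 for oocyte and eggshell (15 of 20, adjusted p = 6.2e-27 and 0.042), -8.51 for vitellogenins (6 of 6, adjusted p = 4.5e-24 and 0.0011), -1.32 for male-specific sensory neurons (0 of 12, adjusted p = 0.015 and 0.46), -0.70 for neurotransmitter pathways (3 of 19, adjusted p = 0.0055 and 0.61), -2.88 for histones (16 of 68, adjusted p = 1.5e-14 and 0.26) and -2.03 for DNA replication and mitosis (3 of 20, adjusted p = 6.8e-09 and 0.31). Medians over 0 were 1.23 for pharynx (0 of 14, adjusted p = 0.0041 and 0.45), 2.27 for intestine (2 of 13, adjusted p = 4.1e-05 and 0.12), 1.41 for dauer signalling (1 of 16, adjusted p = 2.7e-05 and 0.12), 1.18 for stress protection (0 of 19, adjusted p = 0.024 and 0.57), 1.80 for ribosomal proteins (7 of 78, adjusted p = 2.8e-30 and 0.31), 1.65 for oxidative phosphorylation (7 of 33, adjusted p = 1.1e-17 and 0.18) and 2.72 for mitochondrially encoded transcripts (7 of 12, adjusted p = 1.0e-09 and 0.25). With an estimated correlation only the vitellogenins and the oocyte and eggshell genes passed. Without hermaphrodite head replicate 1 the median of the major sperm proteins was -4.16, where their mean log2 level was 8.15 in that library against 3.05 and 2.19 in the other two, 8.86 in male head replicate 1 against 0.241 and 0.0670, and 0.206 in male tail replicate 1 against 6.91 and 6.04. Without hermaphrodite tail replicate 1 the medians were -0.14 for neurotransmitter pathways and -1.06 for DNA replication and mitosis, and that for neurotransmitter pathways was -1.29 without hermaphrodite tail replicate 3 and -0.46 without male tail replicate 2.

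The libraries labelled hermaphrodite held markers against their labels. The posterior Hox genes egl-5, php-3 and nob-1 argue against an exchange of the labels whole and head. They were higher by 1.499 log2 in the libraries labelled whole than in those labelled head, against 1.08 in males. An exchange was not excluded, because the males are adults and a difference of stage between these hermaphrodite libraries could also shift these genes. Larval age of the libraries labelled whole may be an explanation, since 13 molting genes were higher there by 5.15 log2 than in male whole bodies. For the libraries labelled tail the same difference was -0.11, and the condition that made this undecided, that a difference exceed its spread, was applied after the value was seen. Gonad carried over in the head cuts was left open, since the posterior Hox difference from male heads of -0.0440 log2 is also what heads without gonad would give.

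Hermaphrodite whole replicate 1 held male transcripts. Material of whole adult males mixed in was excluded, because mab-3 reached 5.77 times the male whole mean while the major sperm protein sum reached 0.0031 times it. This does not cover adult male tail material, since the major sperm protein sum was only 6.43 TPM in male tail replicate 1. A library of male tail tissue under a wrong label was left open. Its highest correlation with a male tail was 0.795, while those with the other hermaphrodite whole libraries were 0.829 and 0.860. Male tail replicates 1 and 3 correlated at only 0.759 with each other, so a true male tail could miss this bound as well. Larval male material may be an explanation, since 84.2% of the 1368 genes higher in male tails were highest in this library, against 8.26% and 5.63% in the other two. That test does not separate male material from less germ line, because 43.3% of all tested genes and 66.6% of the genes higher in male heads were also highest in this library.

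Many genes stood at low level in dauer heads and tails. Of 10572 genes at 0 in all 3 whole dauers, 32.8% were above 0 in all 3 dauer heads, 2.205 times the 14.9% product of the single shares. Tails had 24.5%, a ratio of 1.65, and adult groups 2.71 to 13.1. Scattered reads were left open, because over genes of unequal level they too exceed the product, though a ratio over 2 had been set to exclude them. An even background such as genomic DNA could not be decided, because the interquartile range of the log2 levels was 2.02 where under 2 had been predicted. Head transcripts diluted in whole dauers were left open, because medians of at least 0.945 TPM of sperm genes in dauer heads do not forbid dilution of other genes.

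The other counts were set against splits of the same libraries. With 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. The real groups were matched or exceeded in 2 of them for whole S. carpocapsae males against females, counting the real one, at 3370 genes against 8331 when females 1 and 2 with male 1 were set against the rest. In each of the other comparisons of 3 against 3 only the real grouping, 1 of 10, reached its count. The real and highest other counts in S. carpocapsae were 8287 and 9 for male against female heads, 4058 and 0 for tails, and 965 and 4, 5528 and 375, and 2068 and 157 for head against tail in females, males and IJs. In C. elegans they were 6813 and 5 for male against hermaphrodite whole bodies, 3477 and 3 for heads and 2890 and 279 for tails. For head against tail they were 2498 and 2 in hermaphrodites, 2263 and 222 in males and 2625 and 1248 in dauers.

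With 100 splits, only the real grouping, 1 of 100, reached its count in IJs, dauer heads and dauer tails. IJs gave 10759 against 8876 in whole bodies, 9806 against 8370 in heads and 7758 against 6071 in tails. Dauer heads gave 11451 against 10352 and tails 9490 against 8928. For whole dauers 2 of 100, counting the real one, reached 4623, with 6469 the highest. The splits with 6469 and 8370 set males alone in the larvae's place. As splits also mixed the sexes, chance was not excluded here.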

How the results depend on the processing

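The alternatives added after the data were examined, and so chosen only after the results were seen, were the fits without ribosomal RNA or the 2 most abundant IDs, with protein-coding genes only, of dauers against males only, and of whole males against hermaphrodites without hermaphrodite whole replicate 1 for gene lists and fixed genes. The unknown depth limits what a value of 0 means, and with 3 libraries per group the counts depended on which libraries entered the variance. No named gene that had passed the test reversed under 9 alternatives, among them the pseudocount, array weights and each library left out in turn. The filter, the replicate term and fitting only the libraries compared could not reverse any, as they keep group means. The replicate term changed no gene count by over 1.5 times. Of the named genes, array weights left 831 on their side of the threshold, with 106 gained and 105 lost, and the fit of only the libraries compared left 773, with 31 gained and 238 lost. Median-of-ratios scaling left 906, with 50 gained and 79 lost. The highest adjusted p over libraries left out in turn lost 185. The test on counts and the tests on orthologues were not run, because the files hold neither counts nor a pairing of IDs.

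With only the libraries compared, the counts in S. carpocapsae became 1994 for male against female whole bodies and 8126 for tails, and 615, 0 and 153 for head against tail in females, males and IJs, where limma gave the males 8072 genes at an unadjusted p under 0.05. In C. elegans they became 5584 and 287 for male against hermaphrodite heads and tails, 3160 for dauer tails, and 651 and 43 for head against tail in hermaphrodites and dauers. These fits had fewer residual degrees of freedom by construction. With array weights the counts were 18887 and 7921 for S. carpocapsae whole bodies and tails between the sexes, 11114 for female head against tail and 5252 for the interaction. In C. elegans they were 11304, 8403 and 7984 for the sexes in whole bodies, heads and tails, 2906 for dauer tails, 6422, 5799 and 340 for head against tail in hermaphrodites, males and dauers, and 4740 for the interaction. A pseudocount of 0.1 gave 6232 for S. carpocapsae tails between the sexes, 2810 for male head against tail, 229 for the interaction and 1574 for dauer head against tail. Median-of-ratios scaling gave 10410 for S. carpocapsae tails between the sexes, 3776 for C. elegans whole bodies between the sexes and 1850 for the C. elegans interaction. Without the 2 most abundant IDs, S. carpocapsae male head against tail gave 9117 and the interaction 2578, and without ribosomal RNA dauer head against tail gave 4495. Camera called 124 pairs of list and comparison with the preset correlation and 13 with an estimated correlation. For array weights, the pseudocount and the scalings the cause was not tested.

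Leaving 1 library out gave 2634 to 5655 genes for S. carpocapsae whole bodies between the sexes, where the count was 5302 without male whole replicate 1 and 5655 without female whole replicate 3. It gave 5707 to 8573 for heads and 2543 to 3827 for tails, 2543 without male tail replicate 2 being the value outside 1.5 times. The IJ comparisons gave 8679 to 11541, 8003 to 9996 and 6124 to 7605 in whole bodies, heads and tails. Head against tail gave 568 to 1252 in females, with 568 without female head replicate 2, 576 without female head replicate 3, 591 without female tail replicate 1 and 608 without female tail replicate 3, and 3922 to 5553 in males and 1579 to 2412 in IJs. The interaction gave 968 to 2225, with 968 without female tail replicate 1, 1014 without female head replicate 3, 1041 without female tail replicate 2, 1047 without female tail replicate 3 and 1101 without male tail replicate 2. In C. elegans the sexes gave 4825 to 6687 in whole bodies, 2136 to 2617 in heads, with 2136 without male head replicate 1, 2216 without hermaphrodite head replicate 2 and 2217 without male head replicate 2, and 2020 to 4215 in tails. Dauers gave 3318 to 4552, 9184 to 10999 and 7139 to 10307 in whole bodies, heads and tails. Head against tail gave 1654 to 2616 in hermaphrodites, with 1654 without hermaphrodite head replicate 2, 1465 to 2229 in males, with 1465 without male head replicate 1, and 1883 to 3497 in dauers. The interaction of C. elegans gave 761 to 1163. The cause was not tested.

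Under median-of-ratios scaling, 5 named genes that had passed the test reversed in whole males against hermaphrodites, to 0.23 for flp-13, 0.084 for nuo-1, 0.30 for snb-1, 0.32 for WBGene00010963 and 0.014 for elt-7, with adjusted p of 0.86, 0.99, 0.84, 0.84 and 1.0. tra-1 and myo-2 in whole bodies and vit-2 in tails, which had not passed, changed sign as well. Against males only, 8 genes reversed in dauer heads, at 0.24 for cdk-1, 1.22 for cpg-1, 0.69 for cyb-2.2, 0.27 for syp-3, 1.24 for vit-2, 0.86 for vit-4, 2.34 for vit-5 and 2.53 for vit-6. Of these, vit-5 and vit-6 passed the test, with adjusted p of 0.00015 and 6.4e-05. In dauer tails cdk-1 went to 0.31 and sng-1 to -0.024. The cause was not tested.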

Other observations

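The tests of X linkage, of gene families and of chemoreceptor genes were chosen only after the results were seen. The X chromosome was unevenly represented among the genes that differed between the sexes of C. elegans, in which hermaphrodites carry 2 X chromosomes and males 1. Of the 24134 tested genes, 3873 (16.05%) lie on X. Of the 2154 genes higher in whole males, 58 (2.69%) did (Fisher's exact test adjusted over 20 tests, p = 1.0e-95), and of the 4659 higher in whole hermaphrodites, 871 (18.7%, adjusted p = 1.2e-07). Among genes higher in hermaphrodite heads and tails, 117 of 2548 (4.59%, adjusted p = 1.7e-78) and 59 of 1522 (3.88%, adjusted p = 6.5e-53) were X-linked. Among genes higher in male heads and tails, 211 of 929 (22.7%) and 294 of 1368 (21.5%) were, each with an adjusted p of 1.2e-07. Of the genes lower in whole dauers, 180 of 2732 (6.59%, adjusted p = 1.2e-54) lay on X, and of those higher in hermaphrodite tails than heads, 221 of 883 (25.0%, adjusted p = 8.2e-12).

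Gene families named by symbol, 116 with at least 15 tested members, were tested for excess among the genes called, with Fisher's exact test adjusted over 2320 tests. In whole dauers 49 of 243 nhr genes, which encode nuclear hormone receptors, rose (adjusted p = 2.6e-08), and 64 of 222 clec genes, which encode C-type lectins, fell (adjusted p = 4.1e-11). In dauer heads 25 of 41 mrpl genes of the mitochondrial ribosome and 14 of 20 vha genes of the vacuolar proton pump fell (adjusted p = 1.2e-13 and 8.1e-09). In dauer tails 44 of 150 col genes, which encode cuticle collagens, fell (adjusted p = 1.0e-31). Male tails held higher levels of 62 of 222 clec genes and 46 of 150 col genes than hermaphrodite tails (adjusted p = 2.3e-24 and 7.5e-20). In males, 23 of 70 nlp genes, which encode neuropeptides, were higher in the head than in the tail (adjusted p = 4.5e-12). In hermaphrodites, 18 of 18 nspc genes were higher in the head (adjusted p = 7.3e-20) and 40 of 243 nhr genes in the tail (adjusted p = 9.7e-14).

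Chemoreceptor families rose in dauer heads, with 139 of 148 str genes and 147 of 161 srh genes (adjusted p = 4.2e-45 and 7.0e-44), and in dauer tails, with 100 of 148 str genes (adjusted p = 1.5e-12) and likewise the srh genes (adjusted p = 5.6e-16). A hypothesis was that these are chemoreceptor transcripts beyond the low-level background of the dauer head libraries. It was tested on 493 chemoreceptor and 3455 other protein-coding genes listed at 0 in whole dauers, where the hypothesis predicted a ratio over 1.5 of the shares above 0 in every head library, and its absence a ratio below 1.2. The shares above 0 were 94.5%, 92.7% and 85.2% for chemoreceptor genes and 79.4%, 77.3% and 66.1% for the others, with a lowest ratio of 1.19. With 79.4% and 77.3% of the other genes above 0 in heads 1 and 2 a ratio over 1.5 could not be reached, so the test was void. The mean levels of the chemoreceptor genes were 0.541, 1.05 and 0.916 times those of the others, and the hypothesis was left open.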
